A study of Mus musculus with 6 samples.

How the data were processed

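RNA was measured in lung cells of 4-month-old female mice with 2 genotypes, Bmi1 wild type and Bmi1 mutant, on 6 Affymetrix Mouse Genome 430 2.0 arrays, 3 per genotype. Per the labels, lungs were digested with dispase and collagenase, red blood cells were lysed, and live cells without CD31 or CD45 on their surface were collected by flow cytometry, a gate that is meant to leave out endothelial and hematopoietic cells. The RNA was amplified to cDNA and labelled with biotin, per the labels. The labels call the arrays of a genotype biological replicates and do not say whether each came from 1 mouse or from a pool, so the p values measure the spread between these samples.

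The deposited values are probe-set intensities on a linear scale, made with Affymetrix Expression Console 1.1, per the submitters' processing notes. The authors' summarization method, background step and detection calls are not given in the sources used here. Each array's trimmed mean intensity lies between 500.0023 and 500.0025, so the arrays were scaled to a common mean before deposit. Such a scaling sets the total signal equal on every array and cannot show a shift of all genes together. The median signal per array ranged from 97.4 to 114, and between 47.7% and 50.3% of probe sets lay below a signal of 100. The ratio of 3' to 5' control signals ranged from 4.85 to 5.94 for Gapdh and from 0.949 to 1.002 for Actb. The genotypes overlapped in both ratios. The number of arrays limits the precision.

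The deposited intensities were turned to log2(signal + 16) with no further scaling. The offset damps the noise of dim probe sets and understates the fold of a gene whose signal is near or below it. The table held 45101 probe sets, of which 64 were control probe sets and were left out. By the platform annotation, 34945 of the others carried 1 gene symbol, 932 carried several and 9160 carried none, and those with several or none entered no gene-level test. The Entrez numbers of 34741 of the single-gene probe sets were found in a RefSeq gene table of assembly GRCm38.p6, which was used only for names and neighbours, and 0 symbols were updated. This left 18193 genes. For the 9010 genes with more than 1 probe set, the probe set with the highest mean log2 value over all 6 arrays stood for the gene. H19 was not analysed here.

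Genes were compared between the genotypes, mutant minus wild type, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the default variance prior, no covariate and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and all adjusted p values of genes come from this limma fit. The standard error beside a log2 difference is limma's moderated one. The prior carried 2.93 degrees of freedom. The Bmi1 probe sets were also compared with a two-sided exact permutation test of the difference of means, which cannot give a p below 0.1 with 3 arrays against 3.

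The tests covered 29 gene lists, written with their 700 entries before the data were examined, of which 649 were measured. Each list was tested with camera in limma at a preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were alternatives. For each list, calls were also counted after adjustment over the list alone. The genes named in the report were chosen by a rule written before the data were examined. It takes Bmi1, up to 15 genes with the greatest rise and up to 15 with the greatest fall among called genes whose groups do not overlap, and up to 4 members with the smallest p of each list. It also takes Cdkn2a, Cdkn1c, Igf2, Dlk1, Meg3, Mest, Peg3, Plagl1, Ndn, Grb10, Cdkn1a, Cdkn2b, Sftpc and Scgb1a1 whatever their values. A gene outside this rule is said to be chosen after its values were seen.

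The gene test was tested on simulated arrays made from the real genes' means and residual spreads, with 200 of the 18193 genes changed by known amounts. Over 20 simulated data sets, 25.4% of genes changed by a log2 of 1, 64.0% of those changed by 2 and 80.1% of those changed by 3 were recovered, 0 in the wrong direction, and on average 6.8 unchanged genes were called. A simulated list of 30 genes shifted by a log2 of 0.8 had an unadjusted camera p under 0.05 in 20 of 20 data sets. Of 19 unshifted lists an average of 0 passed a camera adjusted p under 0.05, a stricter cutoff. The simulated genes were independent of each other, which real genes are not.

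The alternatives were quantile normalization, median centring, offsets of 1 and 64, filters on dim genes, other ways to join probe sets, another variance prior, array weights, the replicate number as a block, marker levels as covariates, other thresholds, and leaving out each array in turn. A covariate of hematopoietic markers and a test without immune cell genes were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.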

Results

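Bmi1 encodes a subunit of Polycomb repressive complex 1, which keeps developmental genes silent. The series compared lung cells sorted as negative for CD31 and CD45 from Bmi1 wild-type mice with the same cells from mice labelled Bmi1 mutant, with 3 arrays per genotype. The comparison asks which genes differ in these cells when Bmi1 is mutated, and the published study of this series concerns imprinted loci, genes expressed from 1 parental copy. Log2 signals correlated between arrays of one genotype at 0.970 to 0.979 and between arrays of different genotypes at 0.957 to 0.973. The first principal component held 39.2% of the variance and separated the genotypes.

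The signal of Bmi1 was not lower in the arrays labelled Bmi1 mutant. One probe set read 1047 ± 102 (SD, n = 3) in wild type and 1446 ± 151 (SD, n = 3) in the mutant-labelled arrays, a log2 difference of 0.46 (exact permutation p = 0.1, the smallest this design allows). The other probe set read 588 ± 83.4 and 665 ± 147 (exact permutation p = 0.7). The gene-level adjusted p was 0.282. The labels call the mutant genotype null but do not say which part of the gene is missing, and a probe outside that part checks nothing. Every direction given here therefore rests on the labels.

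The greatest rises in the mutant-labelled arrays included genes known from neutrophils (Stfa3, Stfa2l1), developmental regulators (Nkx2-2, Tfap2a, Hoxd8) and the imprinted gene Cdkn1c, and the greatest falls included genes known from B cells (Ms4a1, Pax5) and natural killer cells (Ncr1, Klra7). The neutrophil-associated cystatin Stfa3 rose from a signal of 13.5 ± 3.90 to 3043 ± 1919 (SD, n = 3 each), a log2 difference of 6.42. The neural and endocrine transcription factor Nkx2-2 rose from 21.5 ± 4.63 to 812 ± 136, a log2 difference of 4.46 with the smallest adjusted p of any gene (0.00156). The fatty acid binding protein Fabp1 fell from 6313 ± 2050 to 184 ± 79.8, a mean signal 34.3 times lower (adjusted p = 0.00617). Of 18193 genes tested with limma, 75 were higher and 93 lower at an adjusted p under 0.05, and in all 168 the arrays of the genotypes did not overlap. Over all genes, 20.5% did not overlap, against 10% by chance. With median centring of each array the split was 120 higher and 88 lower. The counts moved with single arrays: they were 1 higher and 1 lower without wild-type replicate 2, 3 and 5 without wild-type replicate 3, 10 and 13 without mutant replicate 1, 22 and 39 without mutant replicate 2, 34 and 31 without wild-type replicate 1, and 35 and 41 without mutant replicate 3. With the mean level of fibroblast markers as a covariate, limma called 0 genes, with 1479 at an unadjusted p under 0.05, although all 168 kept their direction. It also called 0 genes with the hematopoietic covariate and with the replicate number as a block, and 16 higher and 22 lower with an offset of 1.

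**Figure D1:**
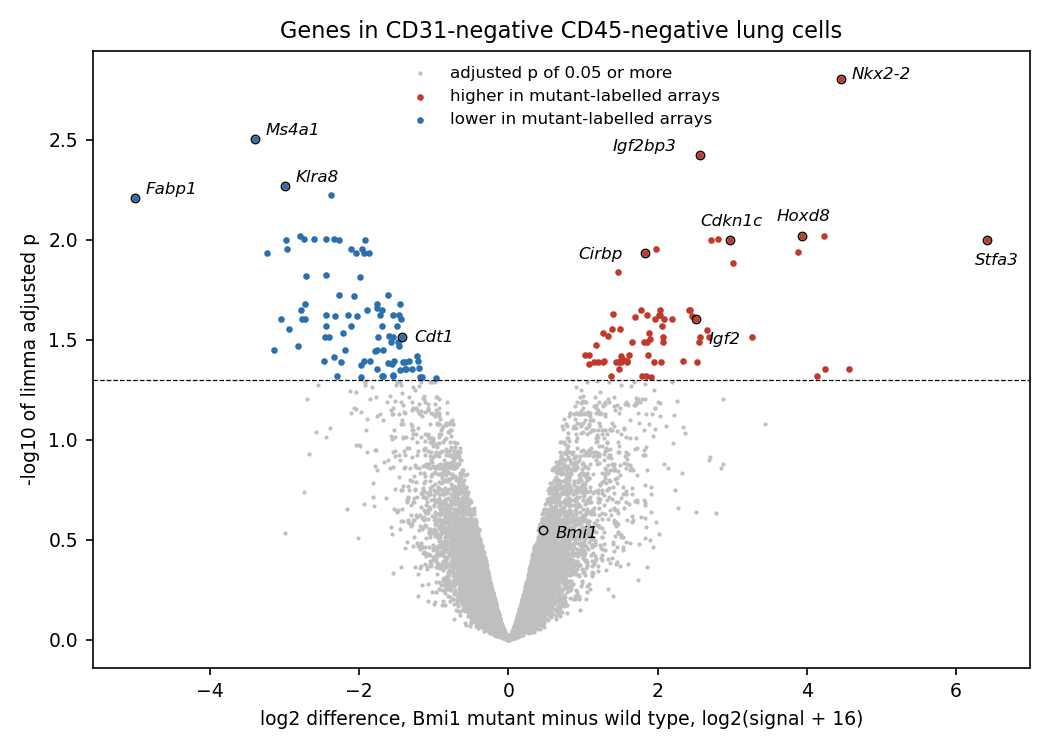
Each point is a gene, with the log2 difference between genotypes on the horizontal axis and -log10 of limma's adjusted p on the vertical axis. The 75 red genes were higher and the 93 blue genes lower in the mutant-labelled arrays, with the dashed line at an adjusted p of 0.05. Bmi1 lies among the grey genes.

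Imprinted genes were higher as a group in the mutant-labelled arrays by camera at its preset correlation but not with an estimated one (adjusted p = 0.254). Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from a signal of 624 ± 51.8 to 5190 ± 1783 (SD, n = 3 each), a log2 difference of 2.97 ± 0.26 (SE, adjusted p = 0.01004). The growth factor Igf2 rose by 2.52 (adjusted p = 0.0249), the noncoding RNA Rian by 2.69 (adjusted p = 0.0307), Mest by 1.95 (adjusted p = 0.0410) and Magel2 by 1.33 (adjusted p = 0.0303). These 5 of 50 measured members were called higher and 0 lower, while 11 were higher and 1 lower when adjusted over the list alone. The list had a median log2 difference of 0.29 and a camera adjusted p of 2.82e-05, against 0.254 with an estimated correlation. Because the published study concerns imprinted loci in these samples, the list is not independent evidence of its direction.

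In the imprinted gene network, a set of imprinted growth regulators expressed together, 3 of 14 measured genes were called higher (8 when adjusted over the list alone), with a median log2 difference of 0.96. The 3 were Cdkn1c, Igf2 and Mest. All 14 also belong to the imprinted genes list, so the result of the network is not separate from that of the list. The network's camera adjusted p was 4.08e-08, and its adjusted p was 0.306 with an estimated correlation. The other 11, which missed the threshold, were Dlk1 (log2 difference 1.95, adjusted p = 0.0563), Peg3 (1.54, adjusted p = 0.173), Ndn (1.32, adjusted p = 0.104), Meg3 (1.04, adjusted p = 0.398), Dcn (0.88, adjusted p = 0.268), Igf2r (0.69, adjusted p = 0.146), Grb10 (0.51, adjusted p = 0.414), Plagl1 (0.32, adjusted p = 0.409), Sgce (0.32, adjusted p = 0.764), Gatm (0.05, adjusted p = 0.951) and Gnas (-0.07, adjusted p = 0.899), of which Dcn, Igf2r, Sgce, Gatm and Gnas were chosen after their values were seen. Fibroblast markers, with a median of 0.64, and smooth muscle and pericyte markers, with a median of 1.07, were higher in the same arrays by camera at its preset correlation but not with an estimated one (adjusted p = 0.566 and 0.456).

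**Figure D2:**
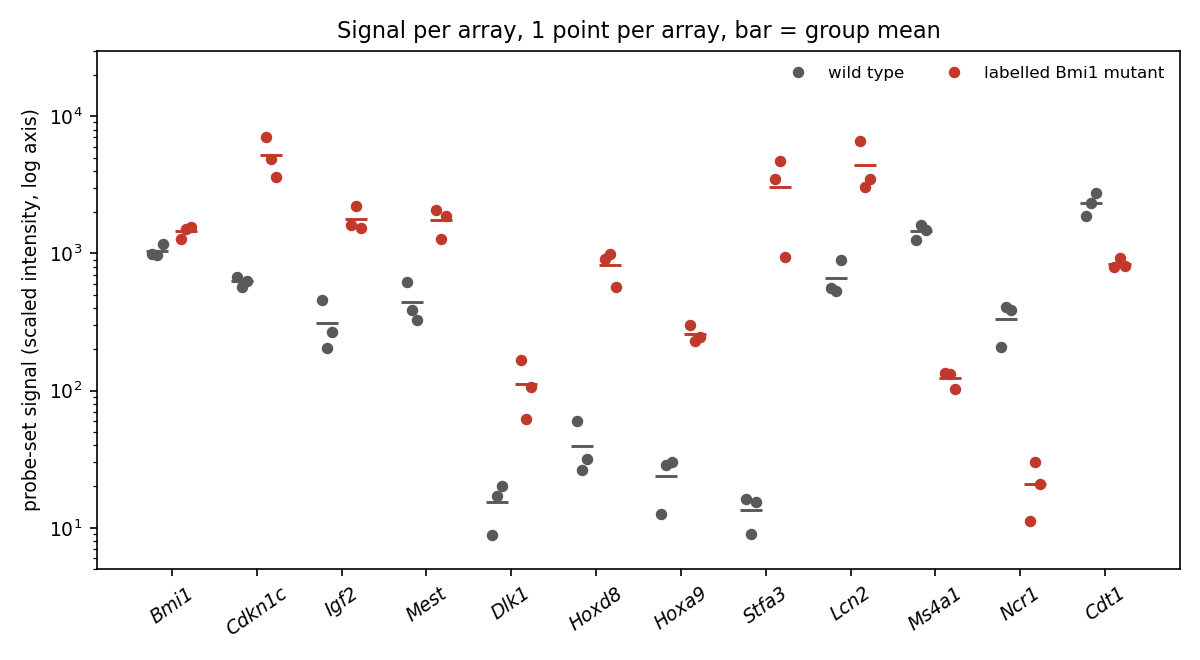
Signal of 12 genes on each array, on a log axis, with 1 point per array and a bar at the mean of each genotype. The arrays of the genotypes do not overlap for any of the genes drawn, and the adjusted p of Dlk1 (0.0563) and Bmi1 (0.282) missed the threshold.

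Several Hox genes, transcription factors that set position along the body axis and known Polycomb targets, rose. Hoxd8 rose from 39.2 ± 18.1 to 819 ± 221 (SD, n = 3 each), a log2 difference of 3.93 ± 0.30 (SE, adjusted p = 0.00951). Hoxa9 rose by 2.81, Hoxa10 by 2.71 and Hoxa13 by 2.43. With Hoxd9 (2.57), Hoxa11 (1.59) and Hoxd1 (1.20), which were chosen after their values were seen, 7 of 33 measured Hox genes were called higher and 0 lower. Adjusted over the list alone, 10 were higher and 1 lower. The list's median log2 difference was 0.73, with a camera adjusted p of 4.08e-08 and an adjusted p of 0.0706 with an estimated correlation. All 7 had a wild-type mean signal below 100, so their folds depend on the offset (the list median was 1.25 with an offset of 1 and 0.33 with an offset of 64), and the list lost its call among genes above the median level (adjusted p = 0.477).

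Among other developmental regulators, Nkx2-2, Tbx15 (log2 difference 1.77) and the neural crest factor Pax3 (2.02) rose and the B cell factor Pax5 fell by 3.04, which makes 3 of 48 measured developmental transcription factors higher and 1 lower. Adjusted over the list alone, 6 were higher and 1 lower. The list had a median of 0.26, a camera adjusted p of 0.0148 and an adjusted p of 0.333 with an estimated correlation, and lost its call with the fibroblast covariate (median 0.15, adjusted p = 0.203) and without wild-type replicate 3 (adjusted p = 0.0846) or mutant replicate 2 (adjusted p = 0.0622). Tfap2a, a regulator of ectoderm and neural crest, was not in a list and rose from 9.11 ± 12.8 to 421 ± 17.2, a log2 difference of 4.23. Of 23 lung development factors, the RNA-binding protein Igf2bp3 was called, with a rise of 2.56 (adjusted p = 0.00375) and a higher signal in each of its 6 probe sets, and adjusted over the list alone 5 were higher and 1 lower. Sox9 (2.22, adjusted p = 0.0748), Igf2bp1 (1.20, adjusted p = 0.0972) and Sox11 (-1.47, adjusted p = 0.153) missed the threshold. That list had a median of 0.26 and a camera adjusted p of 0.0111, and an adjusted p of 0.375 with an estimated correlation, and lost its call with the hematopoietic covariate (median 0.15, adjusted p = 0.141), the type 2 covariate (adjusted p = 0.0759) and the mean of probe sets (adjusted p = 0.0730), and without mutant replicate 3 (adjusted p = 0.0544).

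Several genes known from B cells and natural killer cells fell in the mutant-labelled arrays. The B cell surface protein gene Ms4a1 fell from 1444 ± 170 to 123 ± 17.3 (SD, n = 3 each), a log2 difference of -3.40 ± 0.18 (SE, adjusted p = 0.00314). Among genes of natural killer cells, Ncr1 differed by -3.23, Klra7 by -3.14, Klra8 by -2.996, Klre1 by -2.97 and the transcription factor Eomes by -2.98. The cytotoxic genes Gzmb (-2.77), Fasl (-2.76) and Gzma (-2.48), the B cell genes Fcrla (-2.82), Cxcr5 (-2.73), Cd79a (-2.34) and Cd79b (-1.96), and the lectin gene Cd209a of dendritic cells (-2.73) fell as well. Of 30 measured hematopoietic cell markers 4 were called lower and 0 higher, and adjusted over the list alone 9 were lower and 6 higher. The list had a median of -0.27, a camera adjusted p of 0.00571 and an adjusted p of 0.649 with an estimated correlation. Its call was lost without wild-type replicate 2 (adjusted p = 0.0768), without mutant replicate 3 (adjusted p = 0.0560) and with the fibroblast (adjusted p = 0.0966) and type 2 covariates (adjusted p = 0.0962). Markers of hematopoietic cells were bright in both genotypes despite the sort against CD45: Ptprc, which encodes CD45 and was chosen after its values were seen, read 7716 ± 966 in wild type and 5767 ± 852 in mutant-labelled arrays (SD, n = 3 each, adjusted p = 0.369).

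Other called genes with great differences lay outside the lists. Stfa2l1 (log2 difference 4.57), Asprv1 (3.26) and Stfa3, which neutrophils express, the acute phase genes Saa3 (4.25) and Lcn2 (2.66), and Arg1 (3.88), which encodes an arginase, rose. The spread of these genes was wide among the mutant-labelled arrays, with Saa3 at 4232 ± 4448 against 142 ± 26.5 in wild type (SD, n = 3 each, adjusted p = 0.0442). The anion exchanger gene Slc26a4 rose by 3.02 and the adhesion molecule gene Chl1 by 4.14, while the keratin gene Krt79 fell by 2.93 and the neuropeptide gene Gal by 2.79.

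Proliferation genes were lower as a group by camera at its preset correlation but not with an estimated one (adjusted p = 0.333), and among them the replication licensing gene Cdt1 passed the test by itself. Cdt1 fell from 2327 ± 440 to 844 ± 65.7 (SD, n = 3 each), a log2 difference of -1.43 ± 0.19 (SE, adjusted p = 0.0307). Of 46 measured proliferation genes, 45 lay below 0, 1 was called lower and 12 were lower when adjusted over the list alone. The median was -0.79 and the camera adjusted p 1.05e-15, and the genes of B cells and natural killer cells, lists chosen after the results were seen, had medians of -1.76 and -2.51 in the same arrays. Wild-type replicate 3 had the highest mean of the list (8.84, against 8.26 and 8.40 in the other wild-type arrays and 7.53 to 7.84 in the mutant-labelled arrays), and without it the median was -0.58 (camera adjusted p = 1.10e-11). With the fibroblast covariate the median was -0.44 (camera adjusted p = 1.08e-05), and wild-type replicate 3 also had the lowest mean of the fibroblast markers (9.90). The proliferation list passed in 19 of 21 other settings, among them the hematopoietic covariate. That covariate mixes myeloid and lymphoid genes, which moved apart, so it cannot stand for lymphocytes alone. Cenpe (-1.46, adjusted p = 0.0745), Bub1 (-1.38, adjusted p = 0.118) and Kif11 (-1.19, adjusted p = 0.0744) had the next smallest p.

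Bmi1 is known to repress the Ink4a/Arf locus, which encodes inhibitors of proliferation. Cdkn2a read 30.1 ± 12.4 in wild type and 79.1 ± 22.1 in the mutant-labelled arrays, a log2 difference of 1.06 ± 0.28 (SE, n = 3 each, adjusted p = 0.158). Cdkn2b differed by 1.54 (adjusted p = 0.0880) and Cdkn1a by 0.12 (adjusted p = 0.833). Of 8 measured inhibitors of cyclin-dependent kinases, Cdkn1c was called and 3 were higher when adjusted over the list alone. The list had a median of 0.04, a camera adjusted p of 0.0334 and an adjusted p of 0.450 with an estimated correlation, and lost its call without wild-type replicate 1 (median -0.012, adjusted p = 0.197), mutant replicate 1 (adjusted p = 0.0917) or mutant replicate 2 (adjusted p = 0.0809), and among genes above the median level (adjusted p = 0.0793). The 22 p53 targets had a median of 0.05 with 0 called (camera adjusted p = 0.685). The 19 measured Polycomb repressive complex 1 subunits had a median of 0.06 (camera adjusted p = 0.569) and the 11 of complex 2 a median of -0.20 (camera adjusted p = 0.133, and 0.0250 with the mean of probe sets), with 0 called in each.

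Markers of mesenchymal cells were higher as groups by camera at its preset correlation but not with an estimated one (adjusted p = 0.566 and 0.456). Wild-type replicate 1 lay near the mutant-labelled arrays: fibroblast markers had means of 11.1, 10.7 and 9.90 in wild-type replicates 1 to 3 and 11.2, 11.2 and 11.3 in the mutant-labelled arrays, and smooth muscle and pericyte markers 8.92, 8.05 and 7.62 against 9.44, 8.92 and 9.46. The differences of the means were 0.68 ± 0.35 and 1.08 ± 0.42 (SE over arrays). Without wild-type replicate 3 the medians were 0.23 (camera adjusted p = 0.000791) and 0.84. The collagen gene Col1a1 rose from 2344 ± 467 to 6066 ± 1006 (SD, n = 3 each), a log2 difference of 1.37 (adjusted p = 0.0482), and was the called member among 25 fibroblast markers, of which 4 were higher when adjusted over the list alone. Their median was 0.64, with a camera adjusted p of 2.02e-07 and an adjusted p of 0.566 with an estimated correlation. The 19 smooth muscle and pericyte markers had a median of 1.07 with 0 called and 7 higher when adjusted over the list alone. Their camera adjusted p was 8.47e-08 and their adjusted p was 0.456 with an estimated correlation, and their call was lost with the hematopoietic covariate (median 0.49, adjusted p = 0.141). With the fibroblast covariate their median was 0.41 (adjusted p = 0.0115), and with the hematopoietic covariate that of the fibroblast markers was 0.34 (adjusted p = 0.00472). Rgs5 (1.83, adjusted p = 0.0621), Aspn (1.07, adjusted p = 0.0725), Eln (1.13, adjusted p = 0.0794), Cspg4 (1.00, adjusted p = 0.113) and Notch3 (0.80, adjusted p = 0.121) missed the threshold.

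No marker of alveolar, club, ciliated or basal cells was called. Sftpc, the surfactant protein of alveolar type 2 cells, differed by 0.15 (adjusted p = 0.771) and the club cell gene Scgb1a1 by 0.04 (adjusted p = 0.950), a direction that turned with quantile normalization. Alveolar type 1 cell markers had a median of 0.23 (camera adjusted p = 0.0144, and an adjusted p of 0.611 with an estimated correlation), a call lost without wild-type replicate 2 (adjusted p = 0.0814), without mutant replicate 3 (adjusted p = 0.0692) and with the fibroblast (median -0.025, adjusted p = 0.356) and hematopoietic covariates (median 0.08, adjusted p = 0.210), with Pdpn at 1.51 (adjusted p = 0.0530) and Spock2 at 1.42 (adjusted p = 0.0608). Alveolar type 2 cell markers had a median of 0.15 (camera adjusted p = 0.0419, and an adjusted p of 0.649 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.372), wild-type replicate 2 (adjusted p = 0.0814), mutant replicate 1 (adjusted p = 0.134) or mutant replicate 3 (adjusted p = 0.186), and with quantile normalization (adjusted p = 0.161), the replicate block (adjusted p = 0.0956) and the hematopoietic covariate (adjusted p = 0.236). Without wild-type replicate 3 the medians were 0.13 for type 1 and 0.24 for type 2 markers. Both lists had 0 called genes, and adjusted over the list alone 2 type 1 and 0 type 2 markers were higher. Markers of club cells (median 0.21, camera adjusted p = 0.118), ciliated cells (0.08, 0.0881 by camera) and basal cells (0.15, 0.685 by camera) missed the threshold in the fit of all arrays without covariates, with 0 called. Adjusted over the list alone, 3 club cell markers were higher and 1 lower: Lypd2 (1.48), Reg3g (1.20), Scgb3a1 (0.97) and Cyp2f2 (-0.62), with adjusted p over all genes of 0.0733, 0.116, 0.154 and 0.146. The club cell list passed with the type 2 covariate (median 0.30, adjusted p = 0.0121) and without wild-type replicate 1 (adjusted p = 0.0373). The ciliated list passed without wild-type replicate 2 (adjusted p = 0.00884) or mutant replicate 2 (adjusted p = 0.0178), and with the mean of probe sets (adjusted p = 0.0176), an offset of 64 (adjusted p = 0.0471) and array weights (adjusted p = 0.0499). The genes of fatty acid and cholesterol synthesis had a median of 0.36 and a camera adjusted p of 8.86e-05, with an adjusted p of 0.371 with an estimated correlation and 0 called. Their member Lss differed by 1.05 (adjusted p = 0.0513).

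The remaining lists missed the camera threshold in the fit of all arrays without covariates. Antioxidant genes passed with the fibroblast covariate (adjusted p = 0.00143) and without wild-type replicate 3 (adjusted p = 0.0111) or mutant replicate 3 (adjusted p = 0.0203), immediate early and heat shock genes with the type 2 (adjusted p = 0.0215) and hematopoietic covariates (adjusted p = 0.0205), and endothelial markers without wild-type replicate 1 (adjusted p = 0.00415). Endothelial cell markers had a median of 0.04 with the apelin receptor gene Aplnr called at -2.11 (adjusted p = 0.0111). Despite the sort against CD31, the median signal of these markers was 1410 in wild type and 1546 in the mutant-labelled arrays. Neuroendocrine cell markers had a median of 0.07 and a mean of 0.004 while camera gave the lower direction, with Resp18 called at -1.75 (adjusted p = 0.0442). The immediate early and heat shock genes had a median of 0.14, with Hsph1 called at -1.22 (adjusted p = 0.0379). Medians were 0.26 for erythroid markers, 0.04 for mesothelial cell markers, 0.17 for antioxidant genes and NRF2 targets, -0.16 for interferon-stimulated genes, 0.01 for oxidative phosphorylation subunits and 0.05 for neighbours of Bmi1 on its chromosome, with 0 called in each. The sex check genes had a median of -0.11 and a mean of 0.04, with Xist bright in both genotypes (6073 ± 387 and 5396 ± 756, SD, n = 3 each). Of the 29 lists, 13 passed the camera threshold, 11 higher and 2 lower, 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and 6 passed with fry. Those 6 were Hox genes, imprinted genes, the imprinted gene network, lung development factors, developmental transcription factors and fatty acid and cholesterol synthesis. Lists past camera but not fry were proliferation (fry adjusted p = 0.0572), CDK inhibitors (0.0819), smooth muscle and pericyte (0.163), hematopoietic (0.213), fibroblast (0.228), alveolar type 2 (0.228) and type 1 markers (0.297).

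**Figure D3:**
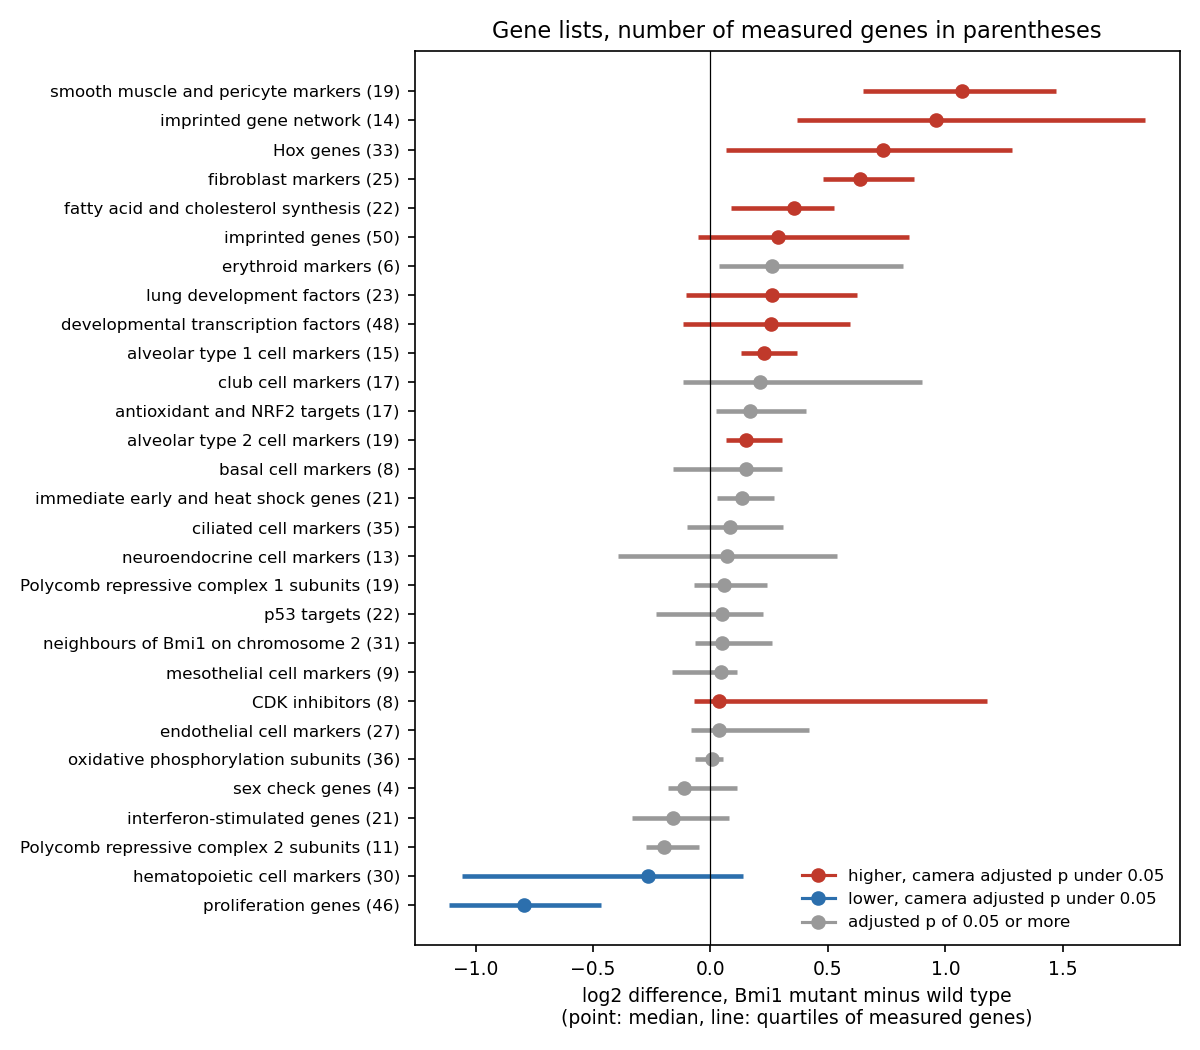
Each row is a gene list, with the median log2 difference of its measured genes as a point and the quartiles as a line. Colour marks lists past a camera adjusted p of 0.05: proliferation genes lie lowest, with a median of -0.79, and smooth muscle and pericyte markers highest, with a median of 1.07.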

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

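The tests of mesenchymal share and of immune carry-over were chosen only after the results they bear on had been seen; a first test of mesenchymal share on the 7 called Hox genes was dropped because they had been picked for their rise, the test on the imprinted gene network was changed with it, and the carry-over test was moved from lists written after the calls to members of a list fixed in advance. Probe sets without a single gene name were outside the gene-level test, and when every probe set was tested with limma 15 of them were higher and 18 lower in the mutant-labelled arrays at an adjusted p under 0.05. The total was 33 of 10092 such probe sets, with 1257 at an unadjusted p under 0.05. The one with the smallest p rose from a signal of 45.9 ± 21.5 to 1073 ± 66.5 (SD, n = 3 each).

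The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes the genotypes, so a difference between them widens the spread within the groups, and few gene calls would follow whatever its cause. For called genes, 1 split, the real one, gave as many as 168, and the highest of the others gave 0. For gene lists, 1 split, the real one, gave as many as 13, and the highest of the others gave 10.

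The first pattern is the rise of Hox genes and of the imprinted gene network. For the 7 called Hox genes, 7 of 7 stayed called under both quantile normalization and median centring. Both rescalings are small next to these rises: the median of alveolar type 2 markers went from 0.15 to 0.094 and 0.25 with them. Array scaling is thus argued against only as far as these rescalings go, for genes picked for their rise. Of 28 dim Hox genes 25% were called higher, against 0.457% of 6782 other dim genes (Fisher's exact p = 1.02e-10). These shares argue against noise of dim signals that is independent between genes. The p counts genes as independent, while the 7 lie in the Hoxa and Hoxd clusters and share the same arrays. It measures no spread between samples, and the 7 were known to be called before the test. A larger share of mesenchymal cells stays open for the 33 Hox genes. With the mean of 44 mesenchymal markers as a covariate their mean rise of 0.89 was 0.86 ± 0.05 (SE), with a 95% t interval of 0.693 to 1.02. The interval stayed above 0 without each wild-type array, although the rise exceeded that of the markers by 0.04 ± 0.36. The covariate cannot decide this, since 28 of the 33 were dim in wild type and a mean near the floor can hardly follow the markers. Wild-type replicate 1, whose markers lay near the mutant-labelled arrays, had a Hox mean of 5.62. The other wild-type arrays had 5.66 and 5.58, and the mutant-labelled arrays 6.49 to 6.56. That goes against share as the whole cause but rests on 1 array. For the imprinted gene network, scaling is argued against to the same extent, as its median stayed at 0.99 or above under both rescalings. A larger share of mesenchymal cells stays open for the network too: the covariate left 0.79 ± 0.17 of a mean rise of 1.14 (95% t interval 0.237 to 1.34), against a difference of 1.18 (interval -0.03 to 2.39) without wild-type replicate 1 and 0.67 (interval -0.15 to 1.49) without wild-type replicate 3, on 2 residual degrees of freedom, and the excess over the markers was 0.29 ± 0.24 (with fibroblast markers as the covariate the network median was 0.69, camera adjusted p = 4.80e-05). A direct effect of the Bmi1 genotype on either group and a change in the kind of mesenchymal cell stay open and were not tested.

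The second pattern is the fall of lymphocyte genes, which the sort against CD45 was meant to leave out. Under both quantile normalization and median centring, the median of 36 lymphocyte genes stayed at -1.56 or lower. The lists of these genes were chosen after the results were seen, and both rescalings are small next to the fall. Array scaling is thus argued against only as far as these rescalings go. Less carry-over of every CD45-positive cell type, acting alone, would lower myeloid and lymphoid genes alike, which was not seen. Among the hematopoietic markers, a list fixed in advance, the level of 12 myeloid genes minus that of 9 lymphoid genes was 2.58 ± 0.27 (SE) higher in the mutant-labelled arrays. The 12 and the 9 were picked from that list after the results had been seen, and the dendritic cell gene Itgax (-0.99) was left out. The contrast was therefore largely known before the test, and its SE does not measure that choice. Less carry-over joined by another change stays open. The myeloid mean differed by 0.65 ± 0.24 and the lymphoid mean by -1.93 ± 0.19 (SE). The myeloid genes were not alike: C1qc differed by 1.92 and S100a8 by 1.46, but Csf1r by 0.25, Cd68 by 0.05, Mrc1 by -0.32 and Marco by -0.38. A shift in which immune cells were carried over may explain the pattern, whether through the sort or through the immune cells present in the lungs of these mice, and neither was tested.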

How the results depend on the processing

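The hematopoietic covariate and the test without immune cell genes were chosen only after seeing the data. In the settings compared gene by gene, all 168 called genes kept their direction wherever they were tested, while the number of calls moved. Since the groups of all 168 do not overlap, the direction was fixed in advance for other offsets and for leaving out 1 array. Outside the leave-one-out settings, values of named genes kept their direction and side of the threshold 808 times, lost the call 223 times and gained one 52 times, and those of gene lists 354, 33 and 8 times. Directions turned 2 times for named genes and 20 times for lists. With 1 array left out, named genes kept both 314 times, lost the call 198 times, gained one 1 time and turned 3 times. Lists then did so 135, 13, 6 and 14 times. Counts of higher and lower genes were 16 and 22 with an offset of 1, 120 and 144 with an offset of 64, 133 and 151 among genes above the median level, 213 and 225 with a trended robust prior, 23 and 27 with alveolar type 2 markers as a covariate, 44 and 47 without immune cell genes, 229 and 226 at an adjusted p under 0.1, and 514 and 485 at an unadjusted p under 0.01 with 1.5-fold change. The count of higher genes was 120 with median centring and 123 above the 25th percentile of level. Leaving out 1 array gave 1 to 35 higher and 1 to 41 lower genes. Limma called 0 higher and 0 lower genes with the fibroblast or the hematopoietic covariate, with 1479 and 2138 genes at an unadjusted p under 0.05. The 7 called Hox genes had a median log2 difference of 2.57, and with the fibroblast covariate, which leaves 3 residual degrees of freedom, a median of 2.60 (range 1.42 to 3.68). Apart from the smaller numbers of genes or arrays tested, the causes were not tested.

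With the replicate number as a block, limma called 0 higher and 0 lower genes, with 2611 at an unadjusted p under 0.05 and 2 residual degrees of freedom. Deviations of same-numbered arrays correlated at 0.073, 0.048 and 0.032, so the numbers were not taken to pair the arrays, although each array correlated best with its own number, a hint from the data only.

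Bmi1 kept its side of the threshold in all settings run on it. Gene lists past the threshold numbered 0 with an estimated correlation and 6 with fry, and the imprinted genes list, with its median of 0.29, then had an adjusted p of 0.254 and 0.0284. The Hox list lost its call among genes above the median level (adjusted p = 0.477).

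Directions turned mostly for values near 0, but the fibroblast covariate also turned the medians of alveolar type 1 (0.23) and club cell (0.21) markers. The fibroblast (0.64) and hematopoietic (-0.27) medians turned only with their own mean as the covariate, which brings a list near 0 by construction. Scgb1a1 differed by -0.032 with quantile normalization and -0.090 with the fibroblast covariate, and by -0.047 to 0.11 when 1 array was left out, and Cdkn1a by -0.0081 to 0.18. List medians turned to -0.019, -0.0289, -0.044 and -0.049 for oxidative phosphorylation (quantile normalization, mean of probe sets, type 2 and hematopoietic covariates), and to -0.040 (above the median level), -0.010 (array weights) and -0.21 (fibroblast covariate) for neuroendocrine markers. The median of p53 targets was -0.0289 with the mean of probe sets. With the fibroblast covariate medians were -0.025 for alveolar type 1, -0.086 for club cell, -0.092 for fibroblast, -0.028 for mesothelial and -0.0102 for endothelial markers. With the type 2 covariate they were -0.069 for mesothelial markers and 0.025 for sex check genes. With the hematopoietic covariate they were -0.037 for mesothelial, -0.26 for endothelial and 0.17 for hematopoietic markers, -0.042 for neighbours of Bmi1 and 0.36 for sex check genes. With 1 array left out, medians ran from -0.012 to 0.22 for CDK inhibitors, -0.087 to 0.23 for mesothelial markers, -0.042 to 0.088 for oxidative phosphorylation, -0.19 to 0.35 for neuroendocrine markers, -0.11 to 0.26 for endothelial markers and -0.26 to 0.085 for sex check genes. Signals near background limit the folds of dim genes: 38 of the higher genes had a wild-type mean and 40 of the lower genes a mutant mean below 100.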

Other observations

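The lists of immune, acute phase, heat shock and clock genes in this part were chosen only after the results had been seen, as were their tests, and a gene that prompted a list adds to its shift. Natural killer cell genes (10 measured) had a median log2 difference of -2.51, B cell genes (14) of -1.76, dendritic cell genes (9) of -1.60 and T cell genes (12) of -0.82. Neutrophil genes (13) had a median of 1.67, macrophage genes (14) of 1.02 and acute phase and airway inflammation genes (12) of 2.05. Genes called lower were 6 of natural killer cells, 9 of B cells, 6 of dendritic cells and 2 of T cells, and genes called higher were 5 of neutrophils, 3 of macrophages and 6 of the acute phase list. Camera adjusted p with an estimated correlation was 0.0194 for natural killer and B cell genes, 0.0138 for dendritic, 0.109 for T cell, 0.0597 for neutrophil, 0.0993 for macrophage and 0.0564 for acute phase genes.

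The macrophage genes did not move as one. The complement gene C1qc differed by 1.92 (adjusted p = 0.0746), the elastase gene Mmp12 rose by 2.08 (adjusted p = 0.0249) and the chemokine Pf4 by 1.87 (adjusted p = 0.0376), while the alveolar macrophage gene Marco differed by -0.38 (adjusted p = 0.628) and Cd68 by 0.05 (adjusted p = 0.937). Among neutrophil genes, Mmp8 rose by 1.70 and Ltf by 1.82, and S100a8 differed by 1.46 (adjusted p = 0.0899).

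Cirbp, an RNA-binding protein gene induced by cold, rose by 1.83 (adjusted p = 0.0116), while the chaperone genes Hsph1 and Stip1 fell by 1.22 and 1.44. A temperature difference may have produced this, and the 12 other heat shock chaperones had a median of -0.23 (limma's camera, unadjusted p = 0.00104), between the bounds set for and against it, so the explanation stays open, and Rbm3, which the test also named, was not analysed here. A different time of day at collection also stays open, since clock genes of the E-box phase had a median of 0.60 and those of the opposite phase -0.29, with 1 of 15 at an unadjusted p under 0.05. Mutant replicate 3 stood apart, near wild type in both clock lists (means of 8.31 and 9.98, against 9.28 and 9.30 and against 9.30 and 9.45 in mutant replicates 1 and 2), and without it the mean differences went from 0.53 to 0.86 and from -0.29 to -0.49. Camera adjusted p with an estimated correlation was 0.0969 for all heat shock chaperones, 0.323 for the E-box phase and 0.296 for the opposite phase.

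Passenger alleles of the strain in which Bmi1 was mutated may differ near the gene. The share of neighbours of Bmi1 at an unadjusted p under 0.05 was 3.23% of 31, against 14.6% of other genes (Fisher's exact p = 0.0763). A broad effect of linked alleles on these neighbours was thus not seen, but the share cannot speak to an allele that acts on 1 or a few genes. The dim neighbour Cubn read 49.1 in wild type and 7.68 in the mutant-labelled arrays, a log2 difference of -1.46 (limma adjusted p = 0.0516). It was lower when adjusted over the list alone, but only 1 of its 2 probe sets went that way.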
